A study of Mus musculus with 12 samples.

How the data were processed

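Lung RNA of 12 mouse samples was sequenced, 4 from each of 3 groups that the labels name as saline control, AE-PF model and ND-RHL-treated AE-PF. Per the labels' protocols, total RNA was extracted with TRIzol and cleaned on RNeasy columns, polyadenylated mRNA was captured on oligo(dT) beads, libraries were made with the NEBNext Ultra kit and sequencing was done on a DNBSEQ-G400 instrument. Groups and replicate numbers were taken from the sample titles, and each column of the table was matched to a sample by its name. The labels do not say that replicates were separate animals, so the p-values below measure the spread between these samples, part of which may be technical.

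The authors deposited 1 table of FPKM values (fragments counted to a gene, scaled by gene length and by the library's total) for 35599 genes in all 12 libraries, without pooling. The submitters' processing notes name FastQC, Trim Galore 0.6.6, STAR 2.7.9a, featureCounts of Subread 2.0.1 and DESeq2 1.30.1, without a role or an order for each, and the builds GRCm38 and mm10. How reads that match several genes were counted is not given in the sources used here, nor is the strand setting. Values of near-identical genes (such as Hspa1a and Hspa1b, the haemoglobin genes and the immunoglobulin constant genes) and of genes that overlap on opposite strands are therefore less certain than others. The gene positions in the table were not those of GRCm38: of 34725 genes found by identifier in the GENCODE M21 annotation of GRCm38, 731 had the same start. Coordinates are therefore given from that annotation, matched by gene identifier, and no position from the table is printed.

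The depth of each library was worked out from the FPKM values. On short genes of 1 exon, the value times the length falls on whole multiples of 1 fragment, which gives the number of fragments counted in each library. The totals were 16152379 to 21667129 fragments. A gene length that turned every library's value into whole fragments, within 1e-05 fragments, was found for 35584 genes (99.96%). In a test on simulated data, 99.9% of 1999 simulated genes were recovered exactly. For a gene of 1 kb, 3 fragments correspond to an FPKM of 0.14 to 0.19, depending on the library. This floor covers counting error only. FPKM of a group is given as the mean ± SD over its 4 libraries.

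Because the table holds FPKM, the comparisons used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend, 2-sided tests and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p of 0.05. Genes with an FPKM of at least 1 in at least 4 libraries were tested, which left 15164 genes, and all 12 libraries shared 1 estimate of the spread with 9 residual degrees of freedom. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Every adjusted p of a single gene is from this limma fit. The plan for raw counts (a count test and its alternatives) did not apply to this table.

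Tested on simulated data for AE-PF against saline, with 14749 genes passing the filter, limma found 51 of 94 genes changed 2-fold (54.3%) and 94 of 95 genes changed 4-fold (98.9%), with 13 other genes called. With no gene changed it called 0 genes. The median log2 change recovered for the 4-fold genes was 1.7. For the same comparison, limma-voom found 62 and 93 of these genes, with 5 others called and 0 calls with no gene changed. In a separate simulation over 14770 genes for this comparison, the gene list test found 2 of 2 raised lists and called 0 of the others. Each gene was drawn independently of the others there. It therefore does not show how often the list test calls unchanged lists whose members vary together.

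Before the data were examined, 34 gene lists were fixed, covering matrix and signalling genes, immune, epithelial, endothelial, mesenchymal and muscle cell markers, pathway genes, markers of adjacent tissues and technical sets. They were tested with camera of limma, with the correlation between genes preset at 0.01 and adjustment over the 34 lists of a comparison. Members past the threshold were counted over all genes tested and adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. After the data had been seen, an exact permutation test of each list's score (the mean log2 value of its members in a library, minus the saline mean) was added. With 4 libraries against 4 there are 70 labelings, and the smallest exact p is 0.0286. A further 7 lists were written after the values were seen and are used only in the closing part and where named as such.

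Named genes followed a rule fixed before the data were examined. For AE-PF against saline and ND-RHL against AE-PF they were the 6 genes with the largest change in each direction, the up to 3 members with the smallest p of each list past the test, and 15 fixed genes. The largest changes had to have an adjusted p under 0.05, a mean FPKM of at least 1 in a group and no overlap between the libraries of both groups. Symbols that were numbered gene models or antigen receptor segments were left out. For ND-RHL against saline the rule gave the 3 largest changes in each direction and the fixed genes. Il6, a fixed gene, was below the filter and was not tested. Of the genes that the rule named, 2 are not reported here singly, although they count in the totals of genes, lists and checks.

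Comparisons that share libraries share their chance values. The overlap of 2 comparisons was therefore set beside 20 simulations of unchanged groups, beside the overlap of independent lists, and beside the values after the shared libraries had been divided between both comparisons in each of the 6 possible ways. Libraries of a group were compared pairwise by a chi-square of their recovered fragments per degree of freedom. The closest pair, AE-PF libraries 3 and 4, had 3.59 and the other pairs 10.11 to 76.58, so no pair was as close as counting error alone would give. This does not show that they came from separate samples, and all 12 were used as the labels give them.

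The alternatives fixed beforehand were pseudocounts of 0.1 and 0.01, no filter, an FPKM minimum of 5, an equal FPKM total per library, median-ratio scaling, quantile normalisation, limma without a trend, with a robust prior or with array weights, fits of 2 groups alone, the replicate number as a block, a log2 fold change of at least 1 and leaving out each library. Limma-voom on the recovered fragments, leaving out AE-PF library 2 together with ND-RHL library 4, and the exact test of list scores were added after the data had been seen. A list was counted as reversed when its median changed sign or its test turned direction past the threshold. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No labels gave a sequencing batch, a date or the sex of the animals.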

Results

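Lung tissue was collected at the model endpoint from 3 groups of mice, and the polyadenylated RNA of 4 samples per group was sequenced. The saline group served as control. The AE-PF group modelled an acute exacerbation of pulmonary fibrosis, a sudden worsening of a scarred lung. Its challenge was bleomycin, a drug that scars the lung, and lipopolysaccharide (LPS), a bacterial product that sets off inflammation. The ND-RHL group received the same challenge followed by liposomes that carried nintedanib, an inhibitor of the receptor kinases for PDGF, FGF and VEGF, and dexamethasone, a synthetic glucocorticoid. These liposomes bore hyaluronic acid, the ligand of CD44, and an RGD peptide, which binds integrins. Each library held 16152379 to 21667129 fragments counted to genes, and 14052 to 15020 genes reached an FPKM of 1. Along the first principal component, which held 55% of the variance, saline libraries lay between -40 and -34.6, ND-RHL libraries between -20.4 and 1, and AE-PF libraries between 32.2 and 59.5.

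Transcripts of stratified squamous epithelium and of skeletal muscle set AE-PF library 2 and ND-RHL library 4 apart from the other 10. Krt13, a keratin of the oral and oesophageal lining, reached an FPKM of 899 and 2948 there, and its mean in saline lung was 0.163 ± 0.0709 (SD, n = 4). The skeletal muscle score, a mean log2 value relative to saline, was 4.33 and 5.44 in these libraries and 1.82 in the next highest, saline library 3. Krt13 was singled out after its values had been seen. AE-PF libraries 1 and 2 lay at 58.2 and 59.5 on the first component, and libraries 3 and 4 at 34.8 and 32.2.

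The first comparison asked what the challenge changed in the lung. Genes of scar tissue were far higher in AE-PF than in saline lung. Col1a1, the main chain of fibrillar collagen, rose from an FPKM of 71.2 ± 11.9 to 518 ± 175, and Fn1, which encodes fibronectin, from 45.4 ± 2.13 to 699 ± 205 (SD, n = 4 per group). Spp1, which encodes the secreted protein osteopontin, rose from 52.0 ± 4.74 to 2011 ± 758, and Timp1, an inhibitor of matrix-degrading proteases, from 6.78 ± 0.559 to 177 ± 43.8. Sftpc, the surfactant protein of alveolar type 2 cells, fell from 11820 ± 1218 to 2635 ± 1396, and Cyp2f2, an enzyme of airway club cells, from 718 ± 51.2 to 75.9 ± 31.0. These 6 genes changed 22.5-fold (Timp1), 36.0-fold (Spp1), 14.6-fold (Fn1), 9.95-fold (Cyp2f2), 6.94-fold (Col1a1) and 5.13-fold (Sftpc), with adjusted p of 7.55e-07, 2.62e-05, 1.16e-06, 5.48e-06, 3.56e-06 and 0.000514 by limma.

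**Figure D1:**
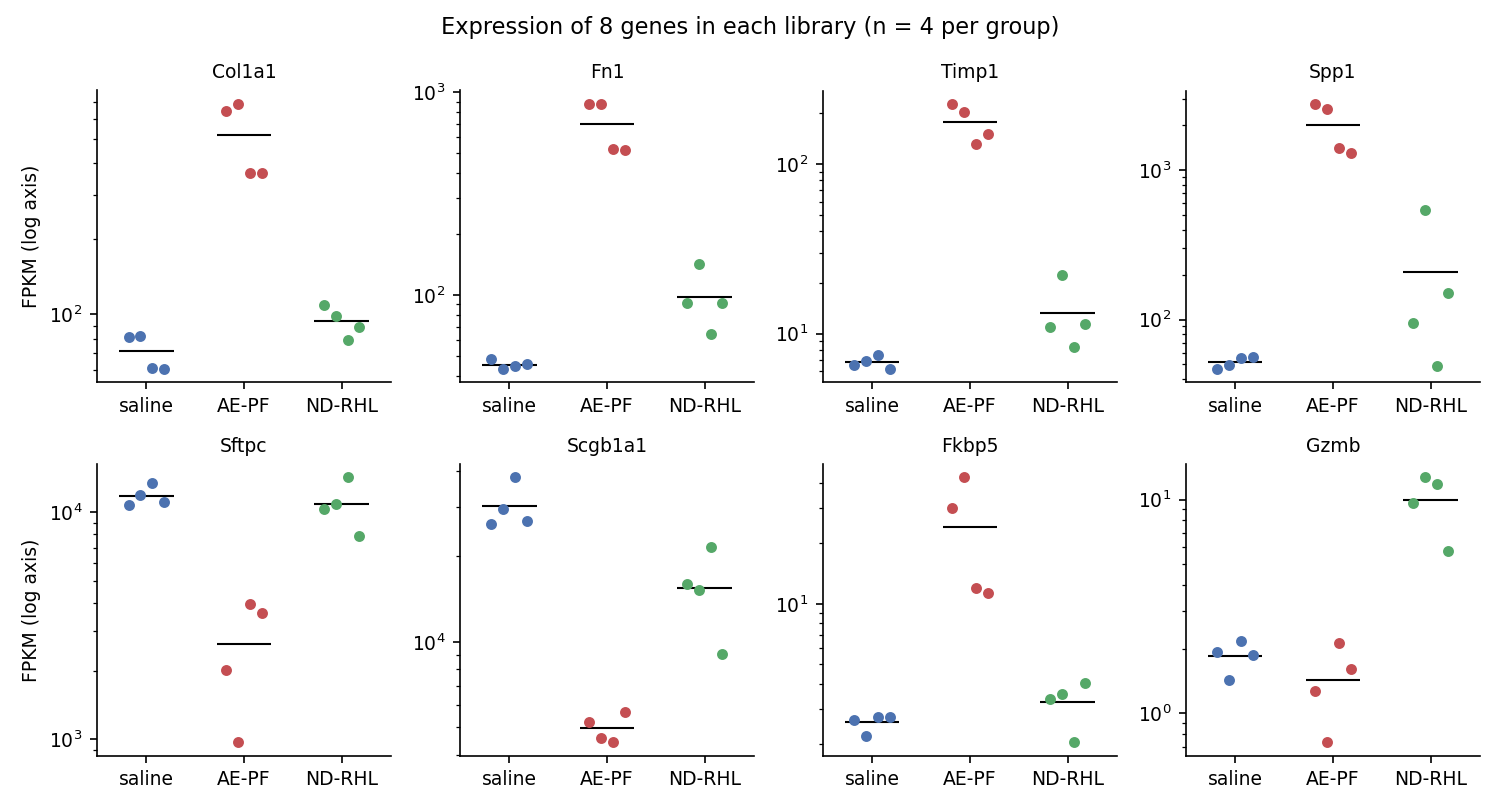
FPKM of 8 genes on a log axis, with 1 point per library and a line at the group mean (4 libraries each of saline, AE-PF and ND-RHL lung). Timp1 lay between 132 and 226 in AE-PF libraries and at 22.0 or less in all others, and Gzmb lay between 5.73 and 12.7 in ND-RHL libraries and at 2.18 or less in the rest.

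Of 15164 genes tested, 8578 changed between AE-PF and saline lung, 4003 of them higher and 4575 lower, and 1520 changed at least 2-fold on the log2(FPKM + 1) scale. The share that was higher was 46.7%, and 63.2% after libraries had been scaled to the same FPKM total, which moved the median of all genes from -0.03 to 0.09 log2. The largest rises were those of Ighg2b (from 0.351 ± 0.244 to 248 ± 293), Saa3 (0.303 ± 0.0818 to 56.7 ± 29.8), Spp1, Ighg2c (0.520 ± 0.360 to 59.2 ± 35.2), Ighg3 (0.303 ± 0.317 to 111 ± 136) and Timp1. Saa3 encodes an acute-phase protein, and the Ighg genes encode constant regions of antibodies. Ighg2b stood at 600 and 377 in AE-PF libraries 1 and 2 and at 7.92 and 5.26 in libraries 3 and 4. The largest falls were those of Cfd (220 ± 140 to 7.83 ± 6.66), Bpifa1 (1001 ± 763 to 29.5 ± 13.6), Hspa1b (120 ± 2.13 to 4.45 ± 0.514), Car3 (81.3 ± 67.9 to 2.702 ± 2.731), Bpifb1 (68.9 ± 40.0 to 2.20 ± 1.011) and Cytl1 (53.1 ± 45.1 to 1.25 ± 0.671), each n = 4. Cfd and Car3 are adipocyte genes, Bpifa1 and Bpifb1 encode secreted proteins of the upper airway, and Hspa1b encodes an inducible heat-shock protein. Bpifa1 was high in the saline libraries where Cfd was (1738, 484, 216 and 1567 beside 377, 123, 83.6 and 298 in libraries 1 to 4). In ND-RHL libraries 1 to 4 Bpifa1 was 1818, 2.525, 86.7 and 435, and Cfd 538, 12.1, 59.7 and 174. Whether differing amounts of dissected tissue lie behind these falls between groups was not tested. The closing part gives only relations of heart, fat and mitochondrial scores within groups.

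Matrix and signalling genes rose as groups. Of 29 matrix and fibrosis genes tested, 28 rose and 0 fell (28 also when adjusted over the list alone), with an adjusted camera p of 1.47e-14 and an adjusted p = 0.335 with an estimated correlation. Col3a1, another fibrillar collagen, went from 93.0 ± 10.7 to 439 ± 103 and Mmp14, a membrane protease, from 15.5 ± 1.19 to 88.7 ± 17.1 (n = 4). Acta2, the actin of smooth muscle and myofibroblasts, did not pass, at 195 ± 19.6 and 225 ± 87.1 (adjusted p = 0.755). Among 19 TGF-beta pathway genes and targets, 15 rose and 2 fell over all genes and adjusted over the list alone (adjusted p = 4.22e-06; adjusted p = 0.334 with an estimated correlation). Examples were Tgfbi, a secreted matrix protein gene (27.1 ± 2.27 to 96.44 ± 13.99) and the receptor gene Tgfbr2 (45.4 ± 0.983 to 93.8 ± 9.63).

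Of 22 acute inflammatory cytokines and chemokines, 16 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 4.56e-05; adjusted p = 0.334 with an estimated correlation). Ccl12, a chemokine for monocytes, went from 1.39 ± 0.696 to 17.3 ± 3.45, and Lif, a cytokine of the interleukin 6 family, from 2.06 ± 0.211 to 9.57 ± 2.05. Cxcl1, a neutrophil chemokine, rose from 0.887 ± 0.278 to 1.76 ± 0.439. Il1b did not pass (19.2 ± 6.94 and 12.7 ± 7.34; adjusted p = 0.161). Il6 was too low to be tested, at 0.314 ± 0.105 and 1.07 ± 0.224. Of 22 monocyte and recruited macrophage markers, 21 rose and 0 fell, also adjusted over the list alone (adjusted p = 2.72e-10; adjusted p = 0.334 with an estimated correlation), among them Ms4a7 (0.905 ± 0.0642 to 9.73 ± 1.16) and the Fc receptor gene Fcgr1 (2.47 ± 0.2496 to 12.0 ± 0.904). Neutrophil markers did not pass as a list: 3 rose and 8 fell of 15 (4 and 8 adjusted over the list alone). S100a8, a calprotectin subunit of neutrophils, fell from 60.6 ± 23.2 to 32.7 ± 10.1 (adjusted p = 0.0396). The S100a8 call was lost in 7 of the 12 fits that left out a library, with an adjusted p of up to 0.114 without saline library 3, and also without a filter (0.0813) and with equal FPKM totals (0.063).

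Markers of alveolar type 2, ciliated, club and secretory and endothelial cells passed as lower. Of 19 alveolar type 2 markers 18 fell (adjusted p = 4.22e-06; adjusted p = 0.536 with an estimated correlation), of 16 ciliated cell markers all 16 fell (adjusted p = 4.22e-06; 0.49 likewise), of 15 club and secretory cell markers all 15 fell (adjusted p = 4.22e-06; 0.412 likewise), and of 20 endothelial markers 14 fell and 1 rose (adjusted p = 0.000382; 0.541 likewise). These counts were the same adjusted over the list alone. Examples were Sftpa1, a surfactant protein gene (1107 ± 118 to 277 ± 93.2), Foxj1, the transcription factor of ciliated cells (47.2 ± 9.36 to 18.1 ± 2.91), Cbr2 of club cells (1864 ± 65.7 to 266 ± 44.8) and Ednrb, an endothelin receptor gene (28.6 ± 1.69 to 7.29 ± 0.538). The Sftpc call was lost with no filter on low values (adjusted p = 0.261), and the Bpifa1 call without saline library 1 (0.0561) or 4 (0.0548). Of 14 genes of the transitional alveolar epithelial state, a damage-associated state between type 2 and type 1 cells, 9 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.0151; adjusted p = 0.49 with an estimated correlation). Cldn4, a tight junction gene, went from 5.91 ± 3.68 to 30.8 ± 7.70. The list's call was lost at an FPKM minimum of 5 (adjusted p = 0.052). Alveolar type 1 markers did not pass as a list (2 rose, 6 fell of 17). Ager, a type 1 gene, was 610 ± 65.8 and 428 ± 162 (adjusted p = 0.084), and passed as lower without AE-PF library 3 (0.048) or 4 (0.0409).

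All 20 cell cycle genes rose, also adjusted over the list alone (adjusted p = 8.74e-11; adjusted p = 0.412 with an estimated correlation), for example Rrm2, a subunit of ribonucleotide reductase (1.64 ± 0.251 to 7.42 ± 0.926). Of 22 glucocorticoid-induced genes, 11 rose and 0 fell in AE-PF lung, a group the labels call untreated (10 adjusted over the list alone; adjusted p = 0.00134; adjusted p = 0.456 with an estimated correlation). Fkbp5, a feedback regulator of the glucocorticoid receptor, went from 2.567 ± 0.2504 to 24.1 ± 15.2 (adjusted p = 0.000112). Its values were 30.2, 42.8, 12.0 and 11.3 in AE-PF libraries 1 to 4. Zbtb16 of the same list was 18.4, 18.1, 4.24 and 3.62 there, and 3.15 to 5.07 in saline libraries. Tsc22d3, another target, did not pass (40.9 ± 4.63 and 52.8 ± 14.6; adjusted p = 0.244). Anxa1 (83.2 ± 8.08 to 237 ± 39.8) and Cdkn1a (24.2 ± 1.99 to 67.1 ± 1.92) of this list also answer to other signals. Of 18 receptors for the liposome ligands and hyaluronan genes, 11 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.0318; adjusted p = 0.334 with an estimated correlation), including Cd44 (28 ± 5.151 to 46.3 ± 4.42), the integrin gene Itgav (7.36 ± 0.688 to 14.6 ± 1.31) and the hyaluronan synthase gene Has2 (0.354 ± 0.199 to 3.65 ± 0.937). This list's call was lost at an FPKM minimum of 5 (0.124), with equal FPKM totals (0.117), with limma-voom (0.0565) and without any 1 of 6 libraries (saline 2, each AE-PF library and ND-RHL 4; 0.0562 to 0.161) or without AE-PF library 2 and ND-RHL library 4 (0.12).

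Of 14 cardiac muscle markers 11 fell (12 adjusted over the list alone; adjusted p = 0.000553; adjusted p = 0.49 with an estimated correlation), of 11 adipocyte markers 8 fell, also adjusted over the list alone (adjusted p = 0.0151; 0.777 likewise), and of 13 mitochondrially encoded genes 6 fell, also adjusted over the list alone (adjusted p = 0.0151; 0.777 likewise). The cardiac gene Myl7 went from 120 ± 41.4 to 7.73 ± 2.93, the lipid droplet gene Cidec from 23.4 ± 14.2 to 0.666 ± 0.581 and mt-Nd2 from 1541 ± 238 to 656 ± 28.2. The adipocyte call was lost with limma-voom (0.071), as were those of Ighg2b (0.151) and Ighg3 (0.16). The lists that did not pass were T cell (3 rose, 0 fell of 18), B and plasma cell (5 and 1 of 16), natural killer cell (0 and 3 of 10), alveolar macrophage (4 and 6 of 16), resident fibroblast (1 and 9 of 17), smooth muscle and pericyte (4 and 4 of 13) and mesothelial markers (2 and 0 of 8). Nor did nintedanib target kinases and ligands (8 and 7 of 21), interferon-stimulated (4 and 1 of 22), oxidative stress response (6 and 1 of 13), circadian clock (6 and 7 of 16), immediate early (4 and 3 of 16) and red blood cell genes (1 and 4 of 8), or mast cell, basophil and eosinophil (0 and 3 of 6), thymus and lymphoid organ (2 and 0 of 6), skeletal muscle (0 and 0 of 6) and sex-linked genes (1 and 0 of 4). In 7 of these lists (B and plasma cell, smooth muscle, nintedanib target, interferon-stimulated, clock, skeletal muscle, mesothelial) the median, mean and test differed in sign. Without AE-PF library 2, T cell markers (adjusted p = 0.00461) and interferon-stimulated genes (adjusted p = 0.0281) passed as higher. T cell markers also did without a filter (adjusted p = 0.0182), and both lists with array weights (0.000578 and 0.00491) and without AE-PF library 2 and ND-RHL library 4 (0.00175 and 0.0353). Resident fibroblast markers passed as lower without AE-PF library 1 (adjusted p = 0.0419), with equal FPKM totals (0.0246), quantile normalisation (0.0262), array weights (0.0336), no filter (0.00695) and fry (0.000117). Mast cell, basophil and eosinophil markers passed as lower with no filter (adjusted p = 0.0417), equal FPKM totals (0.0246) and fry (0.000215), and oxidative stress genes as higher without AE-PF library 3 (0.0469) and with fry (0.047).

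**Figure D2:**
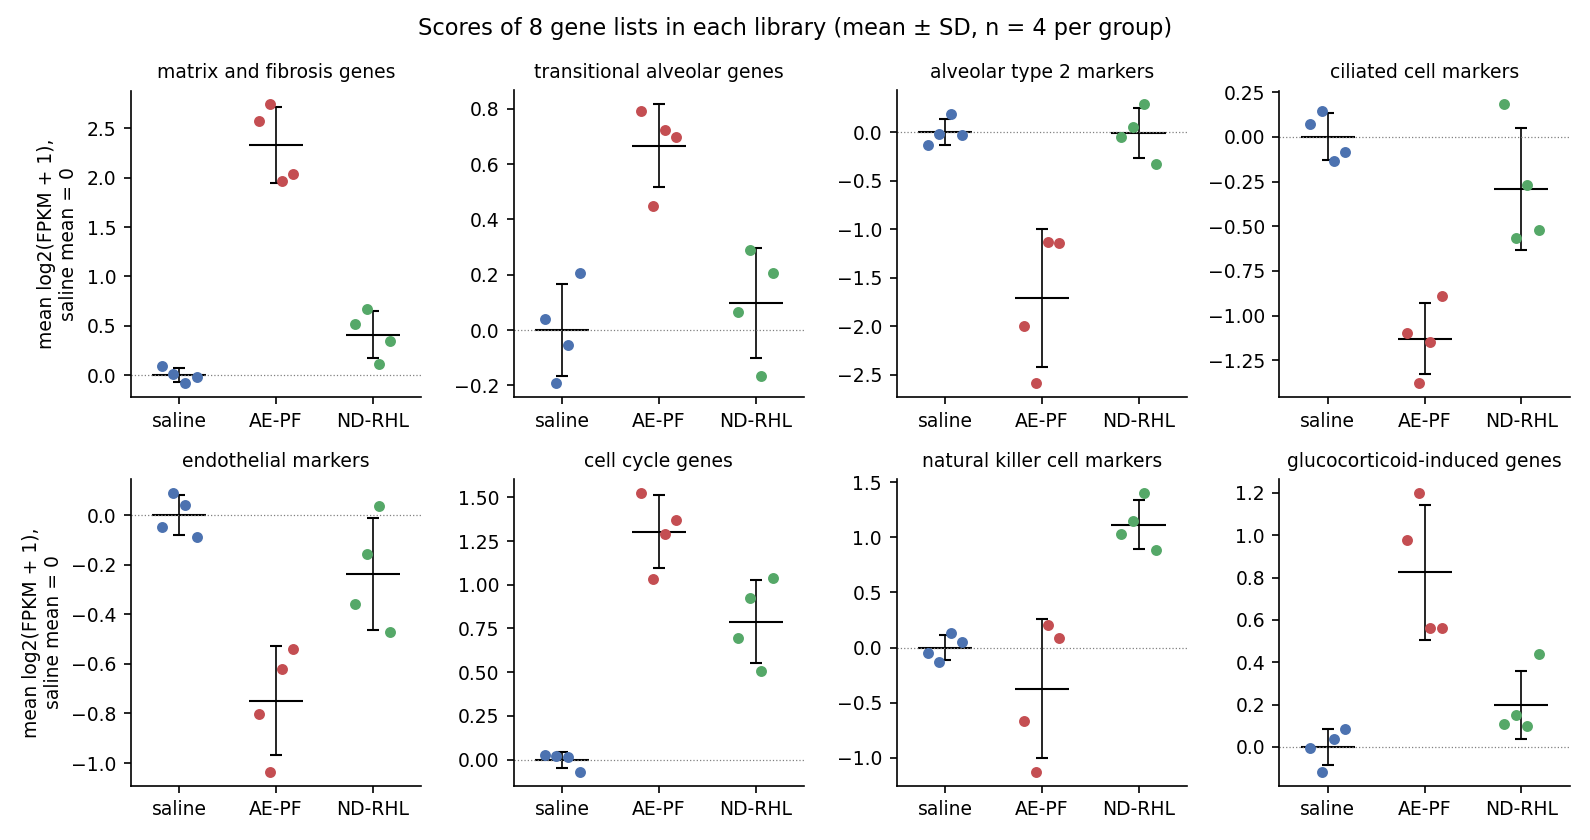
Scores of 8 gene lists per library (mean log2 of FPKM + 1 over the members, with the saline mean at 0), with bars at the group mean ± SD (4 libraries per group). The matrix score was 2.33 ± 0.386 in AE-PF and 0.41 ± 0.24 in ND-RHL lung, and the natural killer cell score was highest in ND-RHL lung at 1.12 ± 0.22.

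The second comparison asked what the liposomal treatment changed in challenged lung. The scar tissue genes were far lower in ND-RHL than in AE-PF lung: Col1a1 fell from 518 ± 175 to 93.8 ± 12.8, Fn1 from 699 ± 205 to 97.4 ± 32.7, Timp1 from 177 ± 43.8 to 13.2 ± 6.05 and Spp1 from 2011 ± 758 to 209 ± 225 (SD, n = 4 per group). Sftpc rose from 2635 ± 1396 to 10860 ± 2635, and Cyp2f2 from 75.9 ± 31.0 to 417 ± 124. Gzmb, a killing enzyme of natural killer and cytotoxic T cells, rose from 1.44 ± 0.592 to 9.96 ± 3.11. The changes were 5.27-fold (Col1a1), 7.16-fold (Fn1), 13-fold (Timp1), 13.5-fold (Spp1), 4.62-fold (Sftpc), 5.59-fold (Cyp2f2) and 4.44-fold (Gzmb), with adjusted p of 3.47e-05, 2.24e-05, 1.05e-05, 0.000545, 0.00162, 0.000102 and 6.62e-05 by limma.

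Between ND-RHL and AE-PF lung 6332 genes changed, 3686 higher and 2646 lower, and 746 changed at least 2-fold. The share that was higher was 58.2%, against 37.6% with equal FPKM totals and 46.4% after quantile normalisation. The largest rises were those of Myl7 (7.73 ± 2.93 to 122 ± 89.1), Hc (12.7 ± 9.36 to 108 ± 28.5), Cidec (0.666 ± 0.581 to 18.9 ± 17.1), Myh6 (5.06 ± 2.63 to 64.3 ± 52.6), Cytl1 (1.25 ± 0.671 to 24.4 ± 22.1) and Actc1 (19.0 ± 4.35 to 175 ± 90.1). Myl7, Myh6 and Actc1 are heart muscle genes and Hc encodes complement C5. The largest falls were those of Saa3 (56.7 ± 29.8 to 2.90 ± 1.84), Spp1, Timp1, Cd177 (92.2 ± 30.8 to 8.69 ± 3.75), Fst (21.2 ± 6.63 to 1.298 ± 0.526) and Grem1 (25.8 ± 11.1 to 2.48 ± 2.04), each n = 4. Cd177 encodes a neutrophil surface protein, Fst an activin inhibitor and Grem1 an inhibitor of bone morphogenetic proteins.

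Of 29 matrix and fibrosis genes 27 fell, also adjusted over the list alone (adjusted p = 2.67e-20; adjusted p = 0.213 with an estimated correlation), including the collagen gene Col8a1 (12.9 ± 2.33 to 2.90 ± 0.206). Of 19 TGF-beta pathway genes 14 fell (15 adjusted over the list alone; adjusted p = 8.12e-08; 0.177 likewise), including Inhba, a subunit of activin (8.52 ± 1.76 to 0.987 ± 0.474), and Pmepa1 (46.2 ± 9.04 to 16.6 ± 2.33). Of 22 inflammatory cytokines and chemokines 14 fell and 1 rose, also adjusted over the list alone (adjusted p = 9.03e-06; 0.213 likewise). The monocyte chemokine gene Ccl2 went from 23.9 ± 8.32 to 2.23 ± 1.09. Of 22 monocyte and recruited macrophage markers 17 fell and 1 rose, also adjusted over the list alone (adjusted p = 1.29e-07; 0.303 likewise), such as the complement gene C1qc (132 ± 27.3 to 38.5 ± 10.9). Cxcl1 fell from 1.76 ± 0.439 to 0.614 ± 0.241 (adjusted p = 0.00235). Acta2, Il1b, S100a8, Ager and Tsc22d3 did not pass, with adjusted p of 0.52, 0.333, 0.462, 0.131 and 0.715. Their ND-RHL values were 196 ± 117, 16.5 ± 4.86, 41.0 ± 13.7, 597 ± 127 and 49.3 ± 16.2 in that order.

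All 10 natural killer cell markers rose, also adjusted over the list alone (adjusted p = 0.000118; adjusted p = 0.405 with an estimated correlation), including the pore-forming protein gene Prf1 (1.15 ± 0.566 to 4.63 ± 1.31) and the receptor gene Klre1 (0.365 ± 0.321 to 1.91 ± 0.492). Of 18 T cell markers 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0282; 0.762 likewise), among them the adhesion molecule gene Cd2 (5.384 ± 2.655 to 15 ± 3.387) and the CD8 genes Cd8a (2.49 ± 0.975 to 5.00 ± 1.28) and Cd8b1 (2.80 ± 1.55 to 8.92 ± 2.87). The T cell call was lost with array weights (0.576), with fry (0.113) and without AE-PF library 1 (0.05), AE-PF library 2 (0.116), ND-RHL library 4 (0.138) or both of the latter (0.442). B and plasma cell markers did not pass as a list (10 rose, 0 fell of 16; adjusted p = 0.0543), but did without AE-PF library 1 (0.0201) or 2 (0.0441) or ND-RHL library 2 (0.037) or 3 (0.0201). They also passed as higher with no filter (adjusted p = 0.00433), equal FPKM totals (0.0045), median-ratio scaling (0.0267), quantile normalisation (0.00993), array weights (0.0258), limma-voom (0.0185) and fry (0.0136).

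Several epithelial lists, the endothelial list and the resident fibroblast list passed as higher. The counts of higher members were 18 of 19 alveolar type 2 markers (adjusted p = 8.12e-08; adjusted p = 0.405 with an estimated correlation), 15 of 16 ciliated cell markers (adjusted p = 2.14e-05; 0.439 likewise), 10 of 15 club and secretory cell markers (adjusted p = 6.5e-05; 0.405 likewise), 12 of 20 endothelial markers with 1 lower (adjusted p = 0.00475; 0.595 likewise) and 6 of 17 resident fibroblast markers with 1 lower (adjusted p = 0.0253; 0.381 likewise), all the same adjusted over the list alone. Examples were Acoxl of type 2 cells (2.026 ± 1.296 to 15.3 ± 6.84), Tppp3 of ciliated cells (38.0 ± 5.19 to 133 ± 19.9), Aldh1a7 of club cells (18.9 ± 3.96 to 53.0 ± 4.62), Plvap of endothelium (109 ± 22.0 to 210 ± 36.0) and Inmt, a methyltransferase gene of alveolar fibroblasts (110 ± 41.6 to 572 ± 174). Of 14 transitional epithelial genes 5 fell, also adjusted over the list alone (adjusted p = 0.00118; 0.381 likewise), including Plaur, the urokinase receptor gene (31.4 ± 4.45 to 15.6 ± 2.65). The Sftpc call was again lost with no filter on low values (adjusted p = 0.334).

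Of 20 cell cycle genes 15 fell (17 adjusted over the list alone; adjusted p = 4.64e-07; adjusted p = 0.405 with an estimated correlation), such as the mitotic kinase gene Aurka (3.84 ± 0.365 to 2.16 ± 0.270). Of 22 glucocorticoid-induced genes 12 fell and 0 rose in the group that received dexamethasone, also adjusted over the list alone (adjusted p = 0.000112; 0.381 likewise). Fkbp5 fell from 24.1 ± 15.2 to 3.24 ± 0.849 (adjusted p = 0.000515) and the kinase gene Map3k6 from 18.1 ± 6.33 to 5.52 ± 1.08. Of 18 receptors for the liposome ligands and hyaluronan genes 9 fell and 3 rose, also adjusted over the list alone (adjusted p = 0.00266; 0.177 likewise), including Cd44 (46.3 ± 4.42 to 32.0 ± 2.74), Itgb5 (98.3 ± 7.07 to 52.6 ± 6.42) and Has2 (3.65 ± 0.937 to 0.413 ± 0.199). The 21 nintedanib target kinases and ligands went both ways, with 7 higher and 8 lower (adjusted p = 0.225).

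The cardiac, adipocyte, red blood cell and mitochondrially encoded lists passed as higher. Higher were 9 of 14 cardiac genes (12 adjusted over the list alone; adjusted p = 0.000237; adjusted p = 0.405 with an estimated correlation), 6 of 11 adipocyte genes (8; adjusted p = 0.019; 0.627 likewise), 7 of 8 red blood cell genes (7; adjusted p = 0.0251; 0.595 likewise) and 6 of 13 mitochondrially encoded genes (7; adjusted p = 0.00478; 0.595 likewise). Hbb-bt, a haemoglobin gene, went from 31.1 ± 14.2 to 109 ± 38.4 and mt-Nd4 from 761 ± 30.5 to 1298 ± 250 (its call was lost with no filter, adjusted p = 0.0562). Without ND-RHL library 4 the adipocyte (0.0622) and red blood cell (0.0827) calls were lost, the latter also at an FPKM minimum of 5 (0.0674). With limma-voom the calls were lost of Cidec (0.0572), Cfd (0.0725), Car3 (0.0878) and Cytl1 (0.103). The Car3 call was also lost without AE-PF library 1 (0.0557) or ND-RHL library 1 (0.0515). The other 13 lists did not pass, with a highest adjusted p of 0.975 for sex-linked genes. In 4 of them (neutrophil, mesothelial, immediate early, sex-linked) the median, mean and test differed in sign. Mast cell, basophil and eosinophil markers passed as higher without any 1 of 4 libraries (saline 3, AE-PF 1, ND-RHL 2 and 3; adjusted p from 0.0327 to 0.0463). This list also passed with no filter (adjusted p = 0.00123), equal FPKM totals (0.0129), median-ratio scaling (0.038), quantile normalisation (0.0304), a fit of the 2 groups alone (0.0456), limma-voom (0.0361) and fry (0.000294). Alveolar type 1 markers passed as higher without AE-PF library 4 (adjusted p = 0.0433) and interferon-stimulated genes without AE-PF library 3 (0.0331) or 4 (0.00532). Alveolar type 1 markers also passed with no filter (adjusted p = 0.0342), equal FPKM totals (0.0472) and quantile normalisation (0.0183). Interferon-stimulated genes also passed with no filter (adjusted p = 0.0169), an FPKM minimum of 5 (0.0248), equal FPKM totals (0.0193), quantile normalisation (0.0262) and limma-voom (0.0292). Oxidative stress genes passed as lower without AE-PF library 3 (adjusted p = 0.0236) and with no filter (0.0333).

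A further comparison asked how far the treatment moved the changes of the model back. Of the 8578 genes that differed between AE-PF and saline lung, 5115 (59.6%) changed in the opposite direction in ND-RHL against AE-PF, 52 (0.6%) in the same direction and 3411 in neither. The count in the same direction was 33 to 62 with single libraries left out. It was 129 with array weights, 32 with fits of 2 groups alone and 34 without a filter. Those moved back comprised 2236 genes that rose and then fell, among them Timp1, Spp1, Fn1, Col1a1 and Saa3, and 2879 that fell and then rose, among them Sftpc, Sftpa1, Cyp2f2, Tppp3 and Ednrb. Independent lists of these sizes would share 698 and 1112 genes. The log2 fold changes of both comparisons correlated at -0.84 across genes, which are not independent replicates, and unchanged groups that share the AE-PF libraries gave -0.5 in simulation. The covariance was -0.29 and the simulated one -0.02. With the AE-PF libraries divided between both comparisons, 3222 to 4257 genes moved back, 13 to 331 changed in the same direction and the correlation was -0.80 to -0.63. Dividing them does not remove a difference common to all AE-PF libraries, such as in dissection or handling. Such a difference would also appear as genes moved back. FPKM totals were 273123 to 279287 in AE-PF, 298097 to 311852 in saline and 291267 to 304407 in ND-RHL libraries.

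**Figure D3:**
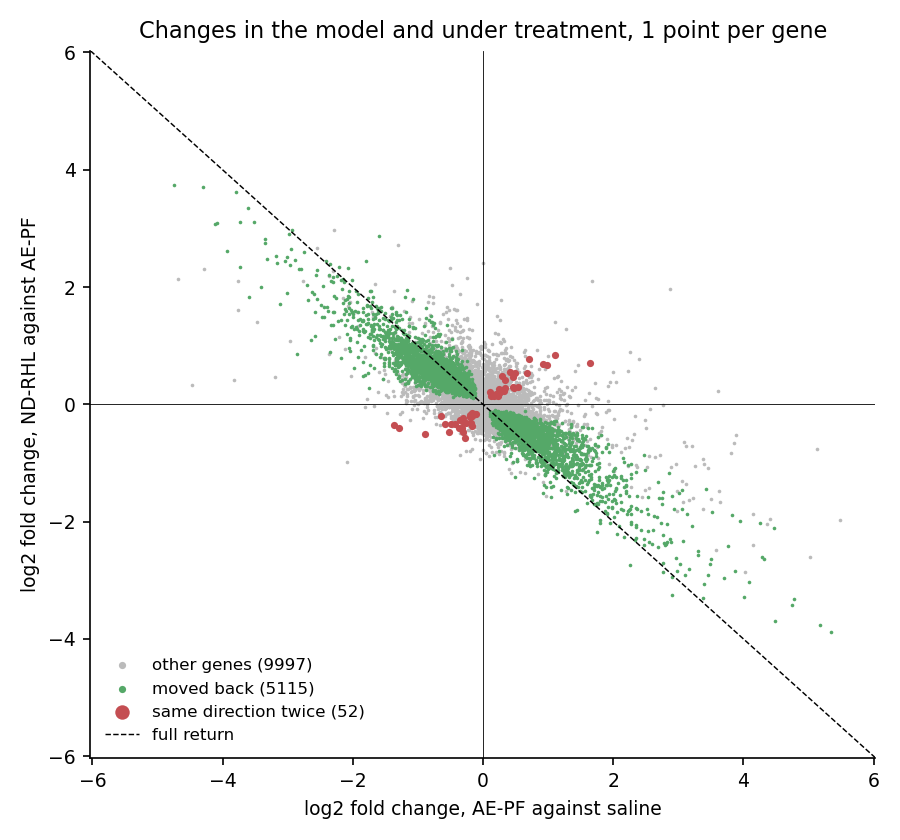
Log2 fold change of each of the 15164 genes in AE-PF against saline (horizontal) and in ND-RHL against AE-PF (vertical), with the dashed line marking a full return. The 5115 genes that moved back lie along the falling diagonal, and the 52 that changed in the same direction in both are drawn in red.

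The third comparison asked what still differed from saline lung after treatment. Some antibody genes were higher and some heat-shock genes lower in ND-RHL than in saline lung. Ighg2c rose from 0.520 ± 0.360 to 54.8 ± 76.7, Jchain, which joins secreted antibodies, from 4.87 ± 2.26 to 64.6 ± 43.2 and Igha from 8.22 ± 3.08 to 84.3 ± 32.3 (SD, n = 4 per group). The largest falls were those of Hspa1b (120 ± 2.13 to 6.27 ± 3.22), Hspa1a (32.4 ± 1.97 to 2.28 ± 1.05) and Cxcl5, a neutrophil chemokine gene (16.5 ± 13.9 to 0.720 ± 0.349). Adjusted p was 0.00197, 0.00224 and 0.00744 for the rises and 3.12e-06, 3.12e-06 and 0.00299 for the falls by limma. The Ighg2c call was lost with limma-voom (0.0659). ND-RHL library 4 held an FPKM of 170 of Ighg2c, and the others at most 18.9.

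In this comparison 3323 genes changed, 2011 higher and 1312 lower, and 240 changed at least 2-fold. The share that was higher was 60.5%, against 43.5% after quantile normalisation and 49.5% with limma-voom. Without saline library 1 the count was 2083 and without saline library 2 it was 2008. Matrix genes remained partly raised: Col3a1 (93.0 ± 10.7 and 151 ± 19.8; adjusted p = 0.0132), Fn1 (45.4 ± 2.13 and 97.4 ± 32.7; 0.0119) and Timp1 (6.78 ± 0.559 and 13.2 ± 6.05; 0.0419) were higher. The Timp1 call was lost with median-ratio scaling (0.0517), without a filter (0.0921), with limma-voom (0.136), and in 8 of the 12 fits that left out a library (up to 0.0906, without saline library 4), as well as without AE-PF library 2 and ND-RHL library 4 (0.0606). Col1a1 (adjusted p = 0.217), Spp1 (0.0993), Acta2 (0.777), Il1b (0.773), Cxcl1 (0.313), S100a8 (0.248), Sftpc (0.822), Ager (0.915), Fkbp5 (0.685), Tsc22d3 (0.54) and Cd44 (0.259) did not pass. Spp1 passed without ND-RHL library 3 (0.0239).

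Immune and proliferation lists were higher, each with an adjusted p = 0.832 with an estimated correlation. Fry lost the matrix (adjusted p = 0.173) and interferon-stimulated lists (0.0973). The counts of higher members were 17 of 22 monocyte and recruited macrophage markers (19 adjusted over the list alone; adjusted p = 9.94e-09), 12 of 18 T cell markers (18; adjusted p = 7.93e-07), 9 of 16 B and plasma cell markers (13; adjusted p = 0.00026), 8 of 10 natural killer cell markers (10; adjusted p = 0.000138), 8 of 22 interferon-stimulated genes (12; adjusted p = 0.00023), 19 of 20 cell cycle genes (19; adjusted p = 1.75e-11) and 8 of 29 matrix and fibrosis genes (8; adjusted p = 0.00549). Of the members of these lists 0 were lower. ND-RHL library 4 was highest for the T cell score (1.56 against 0.757 to 0.949 in the rest of its group) and the B and plasma cell score (2.33 against 0.995 to 1.45). It was also highest for the thymus and lymphoid organ score (1.69 against 0.261 to 0.761). Examples, chosen for this comparison after their values had been seen, were Ms4a7 (0.905 ± 0.0642 to 3.974 ± 1.103; adjusted p = 0.000164), Cd8b1 (2.00 ± 0.578 to 8.92 ± 2.87; 0.00311), Gzmb (1.85 ± 0.312 to 9.96 ± 3.11; 0.00046) and Rrm2 (1.64 ± 0.251 to 5.42 ± 1.12; 0.00019).

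Ciliated cell markers (0 higher, 1 lower of 16; adjusted p = 0.00339), club and secretory cell markers (0 and 3 of 15; adjusted p = 0.00026) and endothelial markers (0 and 5 of 20; adjusted p = 0.00288) were lower as lists, each with an adjusted p = 0.832 with an estimated correlation and each lost with fry (0.283, 0.0973 and 0.215). Adjusted over the list alone, 1, 4 and 5 of their members fell. The club and secretory score was -2.42 in ND-RHL library 2 and -1.055 to 0.216 in the rest of its group. That library was also lowest for the adipocyte score (-2.57 against -1.38 to 1.28). Foxj1 was the ciliated gene (47.2 ± 9.36 to 26.4 ± 6.35; adjusted p = 0.00801), and Ramp2, a receptor activity gene of endothelium, was lower as well (83.3 ± 7.77 to 52.6 ± 9.58; 0.00576). Alveolar type 2 markers did not pass, with 0 of 19 members called. The other 23 lists did not pass either. In 3 of the 24 (alveolar type 1, circadian clock, mitochondrially encoded) the median, mean and test differed in sign. Neutrophil markers passed as lower without ND-RHL library 4 (adjusted p = 0.00416), saline library 1 (0.0247) or saline library 2 (0.00502), and with no filter (0.0328), equal FPKM totals (0.0275) and without AE-PF library 2 and ND-RHL library 4 (0.00421). Thymus and lymphoid organ markers passed as higher with no filter (adjusted p = 0.0341). Without ND-RHL library 1, smooth muscle (adjusted p = 0.0221), cardiac (0.0183) and adipocyte markers (0.0384) passed as lower.

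Of the genes changed in AE-PF against saline, 2552 also changed in the same direction in ND-RHL against saline (1499 higher in both, 1053 lower in both) and 69 in the opposite direction. Independent lists of these sizes would share 531 and 396 genes. Hspa1b, Hspa1a and Ighg2c were among those shared. The log2 fold changes correlated at 0.68 across genes, which are not independent replicates, against 0.50 in simulations of unchanged groups that share the saline libraries. With the saline libraries divided between both comparisons, 834 to 1429 genes changed in the same direction. Dividing them does not remove a difference common to all saline libraries, such as in collection or handling, which the closing part leaves open.

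**Figure D4:**
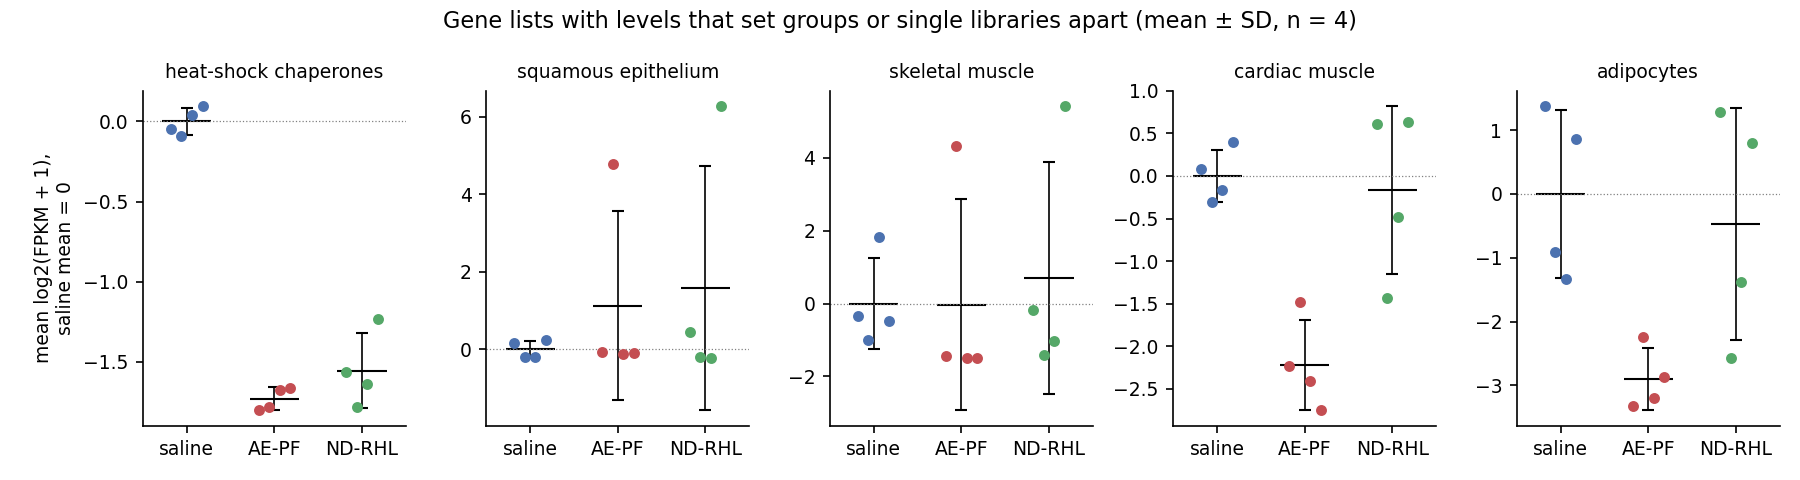
Scores of 5 gene lists per library, with bars at the group mean ± SD (4 libraries per group, saline mean at 0); the heat-shock chaperone and squamous epithelium lists were written after the values had been seen. The chaperone score was -1.73 ± 0.07 in AE-PF and -1.55 ± 0.23 in ND-RHL lung.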

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

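The tests of the squamous epithelium pattern below were chosen after its values had been seen. In each group of 4 libraries, a value was singled out when its gap to the nearest other, divided by the group's range, exceeded Dixon's 95% critical value. Chance singles out about 1 in 20 groups, and 21 of 399 groups were singled out, with about 20 due to chance, so single entries carry little weight. The 21 comprised 5 in saline, 11 in AE-PF and 5 in ND-RHL lung, 8 of them in AE-PF library 2 and 3 in ND-RHL library 4.

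AE-PF library 2 was highest for Saa3 (101 against 37.7 to 45.0 FPKM in the other 3), Inhba (11.1 against 7.37 to 8.01), C1qc (173 against 115 to 123), Hbb-bs (435 against 139 to 178), Cxcl5 (8.94 against 1.097 to 1.545) and the skeletal muscle score (4.33 against -1.50 to -1.45). It was lowest for the mast cell, basophil and eosinophil score (-0.93) and for the share of its 10 most abundant genes (9.24%). ND-RHL library 4 was highest for Ighg2b (78.5 against 5.04 to 11.4), Ighg2c (170 against 15.04 to 18.91) and the glucocorticoid-induced score (0.44 against 0.10 to 0.15). The other ND-RHL entries were Acoxl in library 3 (25.5, highest) and Cxcl5 in library 1 (1.24, highest).

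In AE-PF lung, Itga8 was lowest (19.6) and Aurka highest (4.39) in library 1, and Tppp3 was highest in library 4 (45.7). In saline lung, Actc1 was highest in library 4 (196), Fkbp5 lowest (2.19) and Fam183b highest (26.6) in library 2, the cell cycle score lowest in library 4 (-0.069) and the sex-linked score lowest in library 3 (-0.26).

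Stratified squamous epithelium genes were high in AE-PF library 2 and ND-RHL library 4, as Krt4 (689 and 2408 FPKM) and Sprr3 (126 and 312) show. A squamous change of the airway alone would leave skeletal muscle genes unchanged, but the median excess of 12 such genes over the other libraries of the group was 5.09 and 5.64 log2, which argues against it as the whole cause. Exchanged labels would give AE-PF library 2 a matrix score like that of ND-RHL lung, but it was 2.74, above the highest ND-RHL score of 0.67. A candidate explanation that stays open is tissue with squamous epithelium and striated muscle, such as oesophagus, in these 2 samples: the lower of their skeletal muscle scores exceeded the highest of the other 10 by 2.51.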

How the results depend on the processing

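Limma-voom, leaving out AE-PF library 2 together with ND-RHL library 4, and the exact test of list scores were chosen after the data had been seen. The cause of the moved and reversed results below was not tested. Of 4006 checks of named genes, 3953 gave the same result, 37 lost a call, 4 gained one and 12 changed sign. Of 2847 checks of gene lists, 2616 gave the same result, 70 lost a call, 64 gained one and 97 changed sign. Under the settings for pseudocount, filter, scaling, fit, block and libraries left out, 0 calls of genes turned to the opposite direction and 60.3 to 99.9% of those still tested were kept.

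AE-PF against saline gave 5710 genes at an FPKM minimum of 5. With a log2 fold change of at least 1 the counts were 1520, 746 and 240, and 615 genes moved back. With an estimated correlation 0, 0 and 0 lists passed camera, although 9316, 7625 and 5459 genes had an unadjusted p under 0.05. The exact test passed 22 lists for AE-PF against saline, 0 for ND-RHL against AE-PF and 0 for ND-RHL against saline. In the latter comparisons 16 and 11 lists had no overlap of scores, which gives the smallest exact p possible (0.0286), but so few at that p adjust only to 0.0608 and 0.0884. These 0 counts therefore say nothing about single lists. Fry passed 18, 20 and 5 lists. Of the calls for ND-RHL against saline, fry lost those of matrix (0.173), interferon-stimulated (0.0973), ciliated (0.283), club and secretory (0.0973) and endothelial lists (0.215). With the AE-PF libraries divided between both comparisons, 3249, 3262, 3335, 3267 and 3222 genes moved back in 5 of the 6 ways.

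Leaving out single libraries gave 7539 to 8825 genes for AE-PF against saline, 4788 to 6339 for ND-RHL against AE-PF, 2008 to 3953 for ND-RHL against saline (2008 without saline library 2, 2083 without saline library 1), 3911 to 5236 moved back, and 14 to 16, 16 to 21 and 10 to 13 lists. With the replicate number as a block the counts were 8471, 6061 and 2916 genes, 4909 moved back and 16, 21 and 11 lists, and in AE-PF against saline Il1b passed (0.0447) and the S100a8 call was lost (0.063). With the block, mast cell markers passed in AE-PF against saline (0.0408) and ND-RHL against AE-PF (0.0252), B and plasma cell markers in the latter (0.0322) and neutrophil markers in ND-RHL against saline (0.0368). The labels do not say that the numbers pair the samples. Deviations of 5 of 12 pairs with the same number correlated above 0.1 (-0.387 to 0.397), among them all 4 pairs of saline with ND-RHL lung (0.397, 0.188, 0.114 and 0.173), and 4 of 12 libraries matched best with their own number.

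List medians and gene values that changed sign were all of results that did not pass at first. For AE-PF against saline they were: array weights, B and plasma cell 0.092, natural killer 0.016, smooth muscle -0.099, interferon-stimulated 0.359 (which passed, 0.00491), skeletal muscle -1.07, mesothelial 0.127 and Acta2 -0.144. Without AE-PF library 2 and ND-RHL library 4: B and plasma cell 0.018, smooth muscle -0.061, interferon-stimulated 0.145 (passed, 0.0353), skeletal muscle -1.59 and Acta2 -0.091. Equal FPKM totals: alveolar macrophage 0.075, interferon-stimulated 0.087, clock 0.084, skeletal muscle -0.082 and mesothelial 0.082. Median ratio: interferon-stimulated 0.001. Quantile: interferon-stimulated 0.052 and nintedanib targets -0.017. An FPKM minimum of 5: nintedanib targets -0.034. Limma-voom: interferon-stimulated 0.016, skeletal muscle -0.508 and thymus -0.002. Pseudocount 0.01: skeletal muscle -0.502 and thymus -0.069, and 0.1: -0.341 and -0.028.

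For ND-RHL against AE-PF they were: array weights, smooth muscle 0.012, oxidative stress 0.07, immediate early -0.028, sex-linked 0.022 and Tsc22d3 0.03. Without the 2 libraries: smooth muscle 0.076, oxidative stress 0.022, immediate early -0.016 and sex-linked 0.043. Immediate early genes were -0.064 with equal totals, -0.004 with median ratio and -0.029 with limma-voom, and sex-linked genes 0.026 without a filter. For ND-RHL against saline they were: array weights, alveolar type 1 0.074, type 2 0.082, skeletal muscle -0.042, mitochondrial -0.077 and Ager 0.022. Without the 2 libraries: type 1 0.102, type 2 0.091, oxidative stress -0.01, skeletal muscle -0.645, mitochondrial -0.12 and Ager 0.079. Equal totals gave type 1 0.004 and type 2 0.013. Mitochondrial genes were -0.008 with median ratio, -0.015 with limma-voom and -0.017 with quantile, mast cell 0.09 without a filter and clock -0.164 at an FPKM minimum of 5.

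Ranges over the libraries left out, where a sign changed, were for AE-PF against saline: smooth muscle -0.061 to 0.148, nintedanib targets -0.056 to 0.195, interferon-stimulated -0.135 to 0.145, clock -0.099 to 0.021, skeletal muscle -1.59 to 0.551, thymus -0.175 to 0.307, mesothelial -0.132 to 0.09, immediate early -0.001 to 0.364 and Acta2 -0.091 to 0.325. For ND-RHL against AE-PF: oxidative stress -0.17 to 0.023, skeletal muscle -0.691 to 2.29, immediate early -0.152 to 0.13, sex-linked -0.036 to 0.041 and Tsc22d3 -0.288 to 0.033. For ND-RHL against saline: mast cell -0.186 to 0.131, alveolar type 1 -0.096 to 0.102, type 2 -0.091 to 0.091, oxidative stress -0.01 to 0.184, clock -0.008 to 0.184, cardiac -0.607 to 0.22, skeletal muscle -0.645 to 1.41, adipocyte -1.154 to 0.307, mitochondrial -0.12 to 0.116, Acta2 -0.521 to 0.141, Il1b -0.365 to 0.014 and Ager -0.141 to 0.079. Cardiac (0.0183) and adipocyte markers (0.0384) passed as lower without ND-RHL library 1.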

Other observations

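The tests in this part, the splits of the libraries included, and the 7 lists they draw on were set down after the results had been seen. All 20 heat-shock chaperone genes were lower in AE-PF than in saline lung and 19 of 20 in ND-RHL than in saline lung, with 3 higher and 1 lower between ND-RHL and AE-PF. Hsph1 went from 84.9 ± 2.91 in saline to 8.69 ± 2.68 in AE-PF and 12.4 ± 3.78 in ND-RHL lung, and Dnaja1 from 83.7 ± 3.64 to 23.2 ± 2.72 and 22.5 ± 4.13 (FPKM, SD, n = 4). The 3 activators of the circadian clock were lower in both challenged groups, for example Arntl (7.12 ± 0.277, 3.48 ± 0.340 and 3.34 ± 0.422). Of 5 targets of these activators, 3 were higher in AE-PF and 4 in ND-RHL than in saline lung, for example Dbp (0.606 ± 0.104, 4.16 ± 1.46 and 7.46 ± 2.60). Other clock genes that these activators also drive fell in both, such as Ciart (12.9 ± 1.46, 3.83 ± 0.943 and 5.48 ± 1.05), Cry1 (12.9 ± 0.768, 6.63 ± 1.75 and 4.29 ± 0.592) and Per2 (10.0 ± 0.409, 5.86 ± 1.98 and 4.35 ± 0.734), and of the 16 tested genes of the fixed clock list 6 rose and 7 fell in AE-PF. The cold-inducible genes Rbm3 (16.0 ± 1.13, 44.4 ± 9.40 and 23.7 ± 1.83) and Cirbp (19.5 ± 1.97, 30.1 ± 9.62 and 32.1 ± 4.77) were higher in both.

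Of 12 immunoglobulin constant genes, 9 were higher in AE-PF and 5 in ND-RHL than in saline lung, for example Igkc (56.4 ± 15.5, 1090 ± 890 and 520 ± 398). Of 7 antigen presentation genes 0 passed in any comparison by limma, although their mean score was 0.86 ± 0.062 in ND-RHL lung, 0.31 ± 1.09 in AE-PF lung and 0 in saline lung (exact p = 0.0286 for ND-RHL against saline, n = 4). Since this list was written after the values had been seen, that p carries no weight as a test. Cd74 was 486 ± 25.6 in saline, 669 ± 403 in AE-PF and 904 ± 73.1 in ND-RHL lung. H2-Aa was 97.8 ± 9.53, 161.7 ± 103.5 and 201.8 ± 8.86 in the same order. The limma fit shares 1 estimate of the spread over the 3 groups, and the AE-PF libraries varied widely. The 0 calls therefore do not show that these genes were unchanged between ND-RHL and saline lung.

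Each comparison of 4 with 4 libraries allows 35 splits. For AE-PF against saline the real split gave 8578 genes and the highest other 1, for ND-RHL against AE-PF 6332 and 60, for ND-RHL against saline 3323 and 125, and for genes moved back 5115 and 57. For these 4 counts only the real split gave as many, and 1 of 35 is the smallest share this test can give. A split that mixes differing groups adds their difference to the spread, which lowers its count. The splits also take the samples as independent, which the labels do not say. For gene lists past camera, the real splits gave 15, 19 and 10 lists and the highest others 19, 21 and 20. There 14, 5 and 25 of 35 splits gave as many. Some of these splits hold unequal numbers of both groups and so keep part of the group difference. Camera sets a list against the other genes, so lists that differ can still pass in such splits. These shares therefore neither show nor exclude chance for the list counts.

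Chaperone genes were low in both challenged groups, but in every ND-RHL library their score lay below the lowest of the type 1, type 2, endothelial and fibroblast scores, with a difference of -0.76 or lower (SD in saline lung 0.109), which argues against a changed share of these cells as the whole cause there. In AE-PF lung it stays open, since this difference was 0.19, 0.80, -0.55 and -0.52 in libraries 1 to 4. A lower share of club cells stays open as well: the chaperone score lay above the club score by 0.74 to 1.17 in AE-PF libraries, but the difference was -1.78, 0.64, -0.67 and -0.18 in ND-RHL libraries 1 to 4 (SD in saline lung 0.379). Library 1 thus went against it by far more than that SD and library 3 by less. Library 4 lay within that SD, and library 2 did not go against it. However, the list also holds the upper airway genes Bpifa1 and Bpifb1, at only 2.525 and 0.582 FPKM in library 2. Saline lung held 1001 ± 763 and 68.9 ± 40.0 of them. The club cell genes Cyp2f2 (347 against 718 ± 51.2 in saline lung) and Cbr2 (1254 against 1864 ± 65.7) fell far less there. The score of library 2 therefore does not decide about club cells. Collection of the saline lungs at another clock phase stays open: the score of 5 targets, chosen after the values were seen, minus activators was 2.07 higher in ND-RHL and 1.65 higher in AE-PF than in saline lung (exact p = 0.0286 for ND-RHL, n = 4). Because of that choice, this separation and its p carry no weight as a test. Other clock genes that the activators drive fell, but whether this goes with or against another phase was not tested. Another clock phase cannot be told apart from an effect of the challenge, because it divides saline from both challenged groups, and different handling of the saline lungs, which was not tested, stays open as well.

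The cardiac, adipocyte and mitochondrially encoded lists passed as lower in AE-PF and as higher again in ND-RHL lung, with 11 of 14, 8 of 11 and 6 of 13 members lower and 9, 6 and 6 higher again, but each call was lost with an estimated correlation (adjusted p = 0.49, 0.777 and 0.777, then 0.405, 0.627 and 0.595), and the adipocyte calls also with limma-voom (0.071, lower) or without ND-RHL library 4 (0.0622, higher again). Dilution of resident cells by recruited cells would lower cardiac and endothelial genes alike, but the cardiac minus endothelial score changed by -1.47 (exact p = 0.0286, n = 4; SD 0.388 and 0.75), which argues against dilution as the whole cause. Differing amounts of adjacent heart and fat are a candidate explanation: across 12 libraries, deviations from the group mean of the cardiac and adipocyte scores correlated with r = 0.844 (permutation p = 0.00383; rho = 0.776, p = 0.0311; r = 0.731 without the 2 farthest; adjusted p = 0.00575 over 3 relations). For cardiac and mitochondrial scores r was 0.825 (permutation p = 0.0013; rho 0.832, p = 0.00485; 0.733 without the 2 farthest; adjusted p = 0.0039), and for adipocyte and mitochondrial scores 0.919 (permutation p = 0.0137; rho 0.916, p = 0.0223; 0.895; adjusted p = 0.0137). The cardiac score of AE-PF library 2, which held skeletal muscle transcripts, was -1.49, against -2.75 to -2.24 in the rest of its group. Its Actc1 was the lowest there (13.4 against 18.2 to 23.9). Skeletal muscle may thus have raised this score, and the relations were not computed without AE-PF library 2 and ND-RHL library 4. Because the group means were taken out, the relations describe variation within groups only. They cannot show whether amounts of heart and fat explain the difference between the groups. Mouse pulmonary veins also hold cardiac muscle, so an effect of the groups on these cells stays open, untested.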
